A study of Oryza sativa Indica Group with 8 samples.

How the data were processed

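Messenger RNA was profiled by sequencing of leaf tissue from the salt-sensitive indica rice genotype BRS Ligeirinho in 8 libraries. The plants were germinated for 7 days and then grown in sand in a greenhouse with nutrient solution. The labels place the libraries in 4 groups of 2: control plants that never met salt, plants shocked with salt at the vegetative V4 stage, plants shocked at the reproductive R0-R1 stage, and plants shocked at both stages, called double-shock plants here. Groups and replicate numbers were taken from the sample titles. The salt dose, the length of the shocks and the time between shock and leaf collection are not given in the sources used here. A difference between groups in the time of collection could therefore not be told apart from an effect of the shocks. Nothing in the labels says whether the 2 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

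The authors deposited raw read counts per annotated locus, 1 table per library, with no normalisation. Libraries were made from total RNA with an Illumina TruSeq kit, per the labels' protocols. FastQC 0.11.7, Trimmomatic, STAR 2.7, HTSeq 0.11.1 and edgeR 3.8 are listed in the submitters' processing notes, without their settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so loci that overlap or have near-identical copies carry uncertain counts. The tables hold 55986 loci, of which 55801 have identifiers of the LOC_Os form. In that form the first number is the chromosome and the second orders the loci along it. The tables pair no identifier with a gene name, and the reference gene table used here, of the assembly ASM3414082v1, paired 0 of the 55986. No gene name or coordinate is therefore given. The 38 gene lists fixed before the data were examined were not tested for the same reason. For each comparison at most 2 identifiers that rose and 2 that fell are printed.

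Each table ends in 5 HTSeq summary lines that name no gene. They held 14.97% to 19.2% of the reads listed and were left out of library sizes and tests. The remaining counts per library ranged from 10464740 to 11727657. A count of 3 reads, the upper limit that a count of 0 allows, corresponded to 0.256 to 0.287 CPM (counts scaled by library size), covering counting error only.

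Loci were kept by edgeR's filterByExpr on the 4 groups, which left 18251 loci. The 8 libraries were fitted in 1 model with group as the only term, TMM factors and edgeR 4.0.16 in R 4.3.3. All groups then shared 1 estimate of the spread, with 4 residual degrees of freedom and 4.77 prior degrees of freedom, and the common biological coefficient of variation was 16.7%. Contrasts were tested with the two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment over all loci tested, with calls at an adjusted p below 0.05. The contrasts were the 5 pairwise comparisons below, the interaction of the shocks and the average effect of each shock over the other. CPM values use the TMM factors, and standard errors (SE) of log2 fold changes are the fold change divided by the root of F. The loci named are those with the largest rise or fall among calls whose libraries do not overlap and whose mean in the higher group is at least 5 CPM. These choices were made before the data were examined. Where a library compared had 3 reads or fewer, the ratio of pooled reads is given with a 95% exact binomial interval, which covers counting error only and not the spread between libraries.

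Replicates were compared first. The chi-square of the counts of the 2 libraries per degree of freedom, over loci with at least 10 reads, ranged from 12.99 in the control group to 15.11 in the vegetative group, so no pair was a repeat of 1 library. The replicate numbers in the titles were not taken as pairing libraries across groups.

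The procedure was tested on simulated negative binomial counts with the means, dispersions and library sizes of the data and 200 changed loci. For the reproductive group against control it recovered 42% of loci changed 2-fold and 77% of those changed 4-fold, and 7.75% of its calls were false. For the double-shock group against the reproductive group these shares were 42%, 77% and 8.46%. For the vegetative group against control they were 44%, 79% and 13.4%. For the interaction they were 12%, 61% and 8.75%, and for the average effect of the vegetative shock 62%, 92% and 10.5%. In 20 simulations with no change, the most calls in any contrast was 6.

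Alternatives were RLE factors, no low-count filter, a filter of 1 CPM in 2 libraries, robust quasi-likelihood, the likelihood ratio test, DESeq2 1.42.0, fits on the compared groups alone, a replicate block, a log2 fold change of at least 1, and leaving out each library with the tested loci kept. Where that left a group with 1 library, it was assumed to vary like the other groups. Such fits have less power, so a lost call there need not mean that the result rested on the library left out. A term for the share of multiply aligned reads, fits of 4 against 4 libraries as only 2 groups, and comparisons that each used a different control library were added after seeing the data.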

Results

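Leaf transcriptomes were compared between rice plants that met salt shock never, at the vegetative stage, at the reproductive stage or at both. Each group had 2 libraries, with 10464740 to 11727657 counted reads per library. Between 24120 and 24801 loci had at least 1 read. The most abundant locus, LOC_Os11g47970 on chromosome 11, took 4.39% to 5.17% of the counts of a library, and the top 50 loci took 24.2% to 29.2%. On the log2 CPM scale the control libraries were each other's nearest library (Pearson r = 0.978 across loci), as were the reproductive-shock libraries (r = 0.980). Neither vegetative-shock library was nearest to the other: replicate 1 lay closest to reproductive replicate 2 (r = 0.979) and replicate 2 to double-shock replicate 2 (r = 0.977). Double-shock replicate 2 also lay closest to reproductive replicate 2 (r = 0.979), against r = 0.974 with double-shock replicate 1. The share of reads that aligned to more than 1 place was 13.5% in control replicate 1, 13.6% in double-shock replicate 1 and 13.8% in reproductive replicate 2, against 9.32% to 9.995% in the other 5 libraries.

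**Figure D1:**
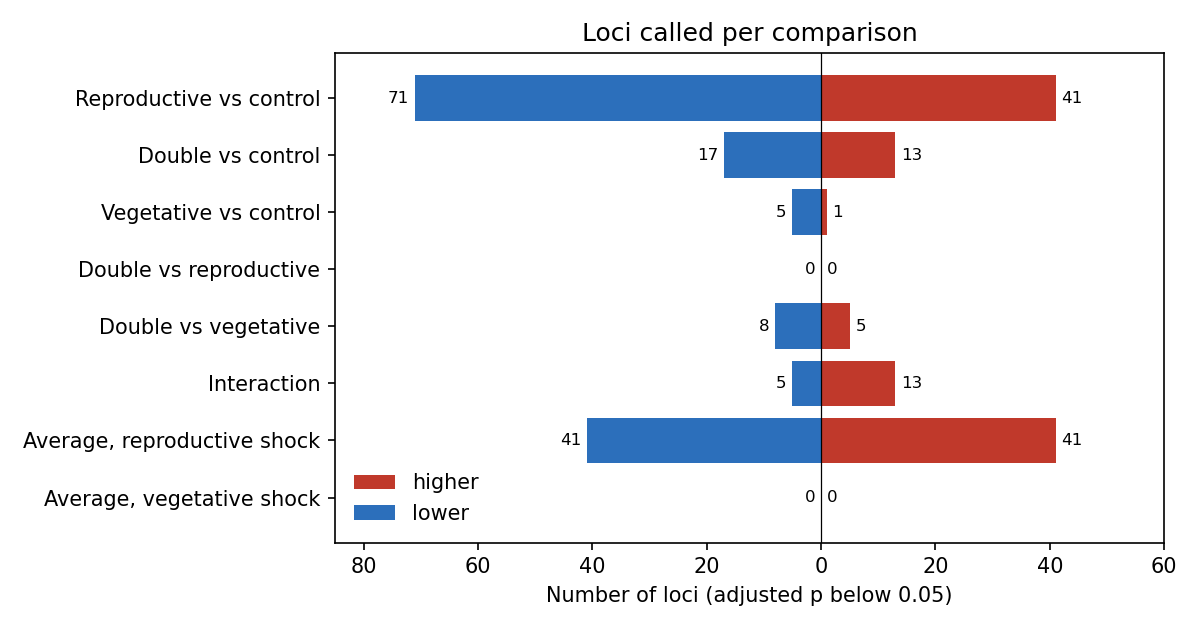
Number of loci called at an adjusted p below 0.05 (edgeR quasi-likelihood test, 18251 loci tested) in each comparison of the 4 groups, with 2 libraries per group; bars to the right count loci that were higher and bars to the left loci that were lower. The reproductive-shock group against control has the longest bars, with 41 loci higher and 71 lower, and neither double-shock against reproductive-shock plants nor the average vegetative effect has any.

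The comparison of the reproductive-shock group with control asks what a single late shock does to the leaf. Of 18251 loci tested, 41 rose and 71 fell, and 83 of these 112 changed at least 2-fold. At an unadjusted p below 0.05 the directions were near balance, with 1278 loci higher and 1317 lower. LOC_Os06g04920 (chromosome 6) rose from 0.185 ± 0.143 CPM in control to 9.81 ± 1.13 CPM (SD, n = 2), with 4 reads in the control group against 212. That ratio was 54.8-fold, with a 95% exact binomial interval of 21.1 to 203 for counting error only. LOC_Os10g42770 (chromosome 10) rose from 0.406 ± 0.100 to 10.1 ± 2.13 CPM (log2 fold change 4.61, SE 0.53, edgeR adjusted p = 0.012). LOC_Os07g41060 (chromosome 7) fell to 1.15 ± 0.022 CPM (log2 fold change -4.86, SE 0.82, edgeR adjusted p = 0.043), from control libraries that themselves stood at 57.8 and 9.53 CPM. Its log2 fold change was -3.04 without control replicate 1 and -5.63 without control replicate 2. LOC_Os08g28710 (chromosome 8) fell from 6.54 ± 1.16 to 0.229 ± 0.048 CPM, a pooled ratio of 28.6-fold with an interval of 12 to 89.5 (edgeR adjusted p = 0.010). The median absolute log2 fold change of the 112 called loci was 1.52. The number of calls fell when any 1 library of the 2 groups was left out, which leaves 1 library in a group and lowers power. Without control replicate 1 the balance of directions shifted toward falls. Without reproductive replicate 1 or 2 the log2 fold change was 5.81 or 5.57 for LOC_Os06g04920 and 4.82 or 4.37 for LOC_Os10g42770. For LOC_Os08g28710 it was then -4.99 or -4.59. DESeq2 called 434 loci, among them all 112, and 212 of the 434 rose. LOC_Os07g41060 lost its call at nearly the same log2 fold change, from -4.84 to -4.88, with robust quasi-likelihood, in a fit of these 2 groups alone, and without any 1 reproductive, vegetative or double-shock library. LOC_Os06g04920 lost its call with robust quasi-likelihood, and both it and LOC_Os10g42770 without any 1 control or reproductive library, as did LOC_Os08g28710 without either reproductive library.

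In double-shock plants, 13 loci rose and 17 fell against control, and 29 of the 30 changed at least 2-fold. LOC_Os06g04920 was again the locus with the largest rise. It stood at 40.7 ± 26.7 CPM (SD, n = 2), with 611 and 259 reads in its libraries against 4 pooled in control. The pooled ratio was 221-fold with an interval, for counting error only, of 85.9 to 812. LOC_Os09g33850 (chromosome 9) rose from 1.45 ± 0.512 to 38.8 ± 19.8 CPM (log2 fold change 4.75, SE 0.54, edgeR adjusted p = 0.022). LOC_Os08g28710 fell to 0.594 ± 0.125 CPM (log2 fold change -3.45, SE 0.42, edgeR adjusted p = 0.025). LOC_Os01g64120 (chromosome 1) fell from 350.3 ± 25.3 to 47.3 ± 10.6 CPM (log2 fold change -2.89, SE 0.22, edgeR adjusted p = 0.0093). Leaving out double-shock replicate 1 left 5 calls, leaving out control replicate 2 left 4 and leaving out vegetative replicate 2 gave 49, while DESeq2 called 232. The balance of directions among calls shifted toward falls without control replicate 1 and toward rises without double-shock replicate 2. Each of these fits leaves 1 library in a group. LOC_Os01g64120 kept its call in every alternative fit run. LOC_Os09g33850 lost its call with robust quasi-likelihood, LOC_Os06g04920, LOC_Os09g33850 and LOC_Os08g28710 lost theirs without either control library, and LOC_Os08g28710 also without either double-shock library.

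The calls of the reproductive-shock and double-shock groups overlapped: 11 loci rose and 16 fell in both, and none was called in opposite directions. Independent lists of these sizes would share 0.0292 and 0.0661 loci. Both comparisons use the same control libraries, and in 20 simulations with no change they shared at most 2 calls. No simulated contrast had more than 6 calls, so this count cannot show what shared controls do to lists of 112 and 30. Their log2 fold changes correlated at r = 0.716 across loci, against 0.503 in those simulations, and their covariance was 0.225 against 0.0731, a difference of 0.152. Of the 41 loci that rose after the reproductive shock 40 were also above control in the double-shock group, and of the 71 that fell all 71 were below. Over both directions this was 111 of 112 (99.1%), where the simulations gave 90.3% for 112 top-ranked loci, with a maximum of 93.8%. The simulations drew loci independently, so they leave out shifts that many loci share in a library. Part of the overlap can come from the shared controls. With 1 control library for each comparison the covariance was 0.148 and 0.167 in the 2 possible assignments, and 4 and 7 calls were shared. The 27 shared calls became 1 without reproductive replicate 1, 3 without reproductive replicate 2 or control replicate 2, 4 without double-shock replicate 1, 14 without double-shock replicate 2 and 42 without vegetative replicate 2.

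**Figure D2:**
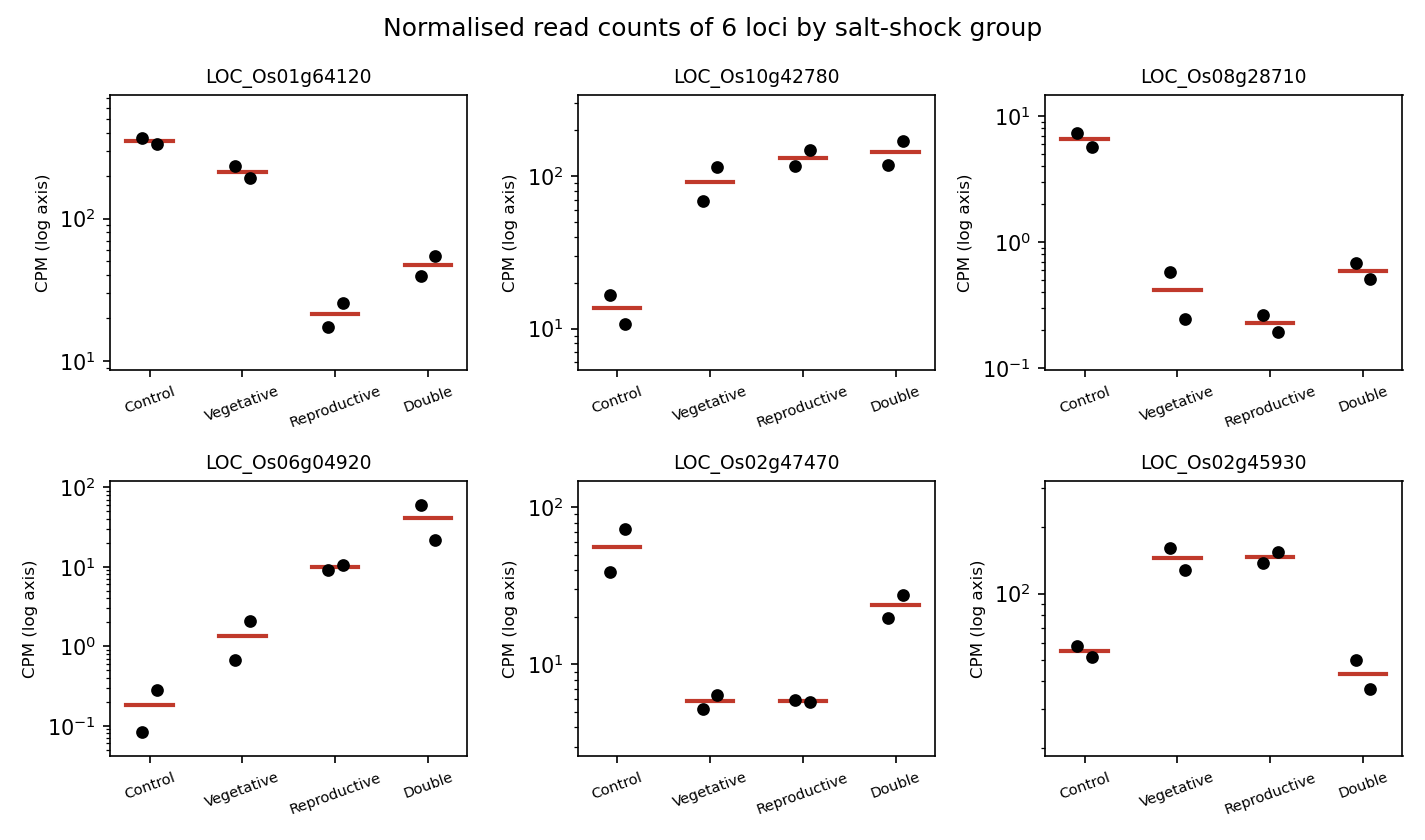
Normalised read counts (CPM, log axis, TMM-scaled) of 6 named loci in the control, vegetative, reproductive and double-shock groups; points are the 2 libraries of a group and the red line is their mean. LOC_Os01g64120 was lowest in the 2 groups with a reproductive-stage shock (21.5 and 47.3 CPM, against 350.3 in control), and LOC_Os02g45930 stood at 144.6 and 146.2 CPM in the single-shock groups against 54.7 in control and 43.3 in double-shock plants.

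The vegetative-shock group against control asks what an early shock alone left in the leaf. Of 6 loci called, 1 rose and 5 fell. LOC_Os10g42780 (chromosome 10) rose from 13.8 ± 4.21 to 91.8 ± 32.5 CPM (SD, n = 2; log2 fold change 2.73, SE 0.32, edgeR adjusted p = 0.043). It was also above control after the reproductive shock (132.1 ± 22.6 CPM, edgeR adjusted p = 0.010) and in double-shock plants (144.1 ± 36.4 CPM, edgeR adjusted p = 0.015). LOC_Os08g28710 fell from 148 pooled reads in control to 9, a ratio of 16.5-fold with an interval of 8.45 to 36.7 (edgeR adjusted p = 0.043). LOC_Os02g47470 (chromosome 2) fell from 56.1 ± 24.3 to 5.82 ± 0.813 CPM (log2 fold change -3.26, SE 0.32, edgeR adjusted p = 0.043). All 6 loci were called in the same direction after the reproductive shock, and 3 of them in double-shock plants. Simulations with no change shared at most 1 call in either overlap, a limit set in part by how few calls they gave. The covariances with the vegetative fold changes were 0.174 for the reproductive-shock group and 0.141 for double-shock plants. With independently drawn loci the simulated values were 0.0726 and 0.0724. With 1 control library for each comparison, the 2 possible assignments gave covariances of 0.109 and 0.0924 for the reproductive-shock group. For double-shock plants they gave 0.0888 and 0.0522, with 56.7% and 48.3% of loci agreeing in sign. Simulated data with no change gave up to 6 calls in a contrast. Without either vegetative or either reproductive library no locus was called, without control replicate 2 there were 2 calls, without either double-shock library 10, without control replicate 1 there were 52, and DESeq2 called 128. With a term for the 3 libraries of high multiply aligned share there were again 6 calls, of which 1 was among these. LOC_Os10g42780 and LOC_Os08g28710 lost their calls in that fit, which has 3 residual degrees of freedom instead of 4, at log2 fold changes of 2.80 (SE 0.37) and -3.83 (SE 0.49), against 2.73 (SE 0.32) and -3.98 (SE 0.44) without the term. All 3 named loci lost their calls in a fit of these 2 groups alone, at about the same fold changes, and LOC_Os10g42780 with robust quasi-likelihood.

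Of the loci called after the reproductive shock, 37 of the 41 that rose (90.2%) and 66 of the 71 that fell (93.0%) lay on the same side of control in vegetative-shock plants. Over both directions this was 103 of 112 (92.0%), and simulated libraries with no change gave 91.7% for 112 top-ranked loci, because the control libraries are shared. Their maximum was 95.5%, so this agreement in sign cannot tell a shared response from shared controls. With 1 control library for each comparison, r across loci was 0.311 and 0.246 in the 2 possible assignments. Deviations of same-numbered libraries from their group means, which carry no shock effect, correlated at up to 0.254 between groups.

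The double-shock group against the reproductive-shock group asks whether an earlier shock alters the leaf of plants shocked later. No locus was called by edgeR, and the smallest adjusted p was 0.096. At an unadjusted p below 0.05 there were 1469 loci, 616 higher and 853 lower, where 913 would be expected by chance. DESeq2 called 72 loci and the edgeR likelihood ratio test 95. LOC_Os02g45930, named for the interaction below, stood at 43.3 ± 9.20 CPM in double-shock and 146.2 ± 12 CPM in reproductive-shock plants (SD, n = 2; log2 fold change -1.76, SE 0.18, edgeR adjusted p = 0.096). LOC_Os06g04920 stood at 40.7 ± 26.7 against 9.81 ± 1.13 CPM (log2 fold change 2.05, SE 0.46, edgeR adjusted p = 0.35). Without double-shock replicate 2, which left a single library in that group, 17 loci were called, and without control replicate 1 there was 1.

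The trace of the early shock was also compared between plants without and with the later shock, in fold changes that share no library. Across loci, the changes of vegetative-shock plants against control and of double-shock against reproductive-shock plants correlated negatively (Pearson r = -0.167, Spearman rho = -0.105, covariance -0.033), and 46.1% of loci agreed in sign. Simulations with no change gave an absolute r of at most 0.031, but loci are not independent replicates and the simulations drew them independently. Deviations of same-numbered libraries from their group means, which carry no shock effect, correlated at -0.153 to 0.254 between groups. Their sign depends on the numbering, and -0.167 is smaller in size than 0.254. This correlation over all loci therefore does not show a reversed trace of the early shock beyond the spread between libraries. The r was -0.0924 without control replicate 2, -0.082 without double-shock replicate 1 and -0.103 without reproductive replicate 2. Without the low-count filter it was -0.026, over 30913 loci instead of 18251. The limit simulated for the filtered loci does not apply to that r, since the added loci have low counts. All 5 loci that fell in vegetative-shock plants against control were higher in double-shock than in reproductive-shock plants, with a median log2 difference of 1.19, although none of those differences was called. The locus that rose, LOC_Os10g42780, kept its sign there (log2 difference 0.13, SE 0.29). Averaged over plants with and without the later shock, the vegetative shock changed no locus by edgeR. At an unadjusted p below 0.05 there were 1054 loci against 913 expected by chance, and DESeq2 called 22 and the likelihood ratio test 18.

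Double-shock plants against vegetative-shock plants give the response to the late shock in plants that had met salt before. There, 5 loci rose and 8 fell. DESeq2 called 113 loci, of which 52 rose, and the likelihood ratio test 164, of which 92 rose. LOC_Os06g04920 rose from 1.37 ± 0.969 to 40.7 ± 26.7 CPM (SD, n = 2; log2 fold change 4.84, SE 0.58, edgeR adjusted p = 0.038). LOC_Os04g49660 (chromosome 4) rose from 3.87 ± 0.0224 to 12.3 ± 0.177 CPM (log2 fold change 1.66, SE 0.20, edgeR adjusted p = 0.038). LOC_Os09g37330 (chromosome 9) fell from 22.6 ± 0.0669 to 4.41 ± 0.390 CPM (log2 fold change -2.36, SE 0.31, edgeR adjusted p = 0.050, just under the threshold). LOC_Os01g64120 fell from 212.8 ± 27.3 to 47.3 ± 10.6 CPM (log2 fold change -2.17, SE 0.22, edgeR adjusted p = 0.026). No locus was called when these 4 libraries were fitted alone, or without double-shock replicate 1, vegetative replicate 2 or either reproductive library. Without vegetative replicate 1 there were 2 calls and without double-shock replicate 2 there were 28, of which 25 rose. With a term for the share of multiply aligned reads there were 6, of which 4 were among these 13. LOC_Os06g04920, LOC_Os04g49660 and LOC_Os01g64120 lost their calls in that fit, with its 3 residual degrees of freedom, at log2 fold changes of 4.30 (SE 0.52), 1.66 (SE 0.22) and -2.20 (SE 0.24). At log2 fold changes that stayed at 4.84 and -2.36, LOC_Os06g04920 also lost its call with robust quasi-likelihood, and LOC_Os09g37330 with RLE factors and with the stricter filter. Without either double-shock library LOC_Os04g49660 and LOC_Os09g37330 lost theirs, and without control replicate 2 LOC_Os06g04920 did.

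**Figure D3:**
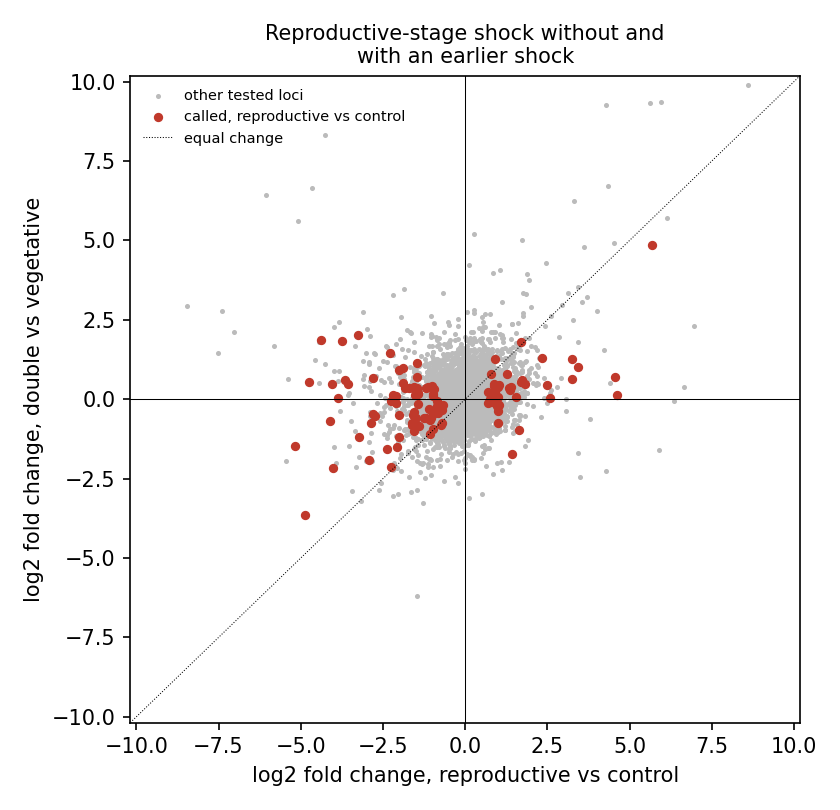
Log2 fold changes of 18251 loci for the reproductive-stage shock, without an earlier shock (horizontal axis, reproductive-shock against control) and with one (vertical axis, double-shock against vegetative-shock); red points are the 112 loci called on the horizontal axis and the dotted line marks equal change. Of the called loci, 31 of the 41 that rose and 40 of the 71 that fell kept their sign on the vertical axis, with most points nearer 0 there.

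The late-shock responses without and with an earlier shock share no library. They correlated weakly across loci (Pearson r = 0.182, Spearman rho = 0.121, covariance 0.0509). Simulations with no change gave an absolute r of at most 0.039, but drew each locus independently, without shifts that many loci share in a library. Deviations of same-numbered libraries from their group means, which carry no shock effect, correlated at -0.153 to 0.254 between groups. An r of 0.182 lies within that range, so this correlation over all loci does not show a shared response beyond the spread between libraries. It does not speak for single loci. Of the 112 called loci, 2 that rose and 3 that fell were also called there in the same direction, and 1 that rose in the opposite. LOC_Os01g64120 fell in both comparisons (log2 fold changes -4.03, edgeR adjusted p = 0.00093, and -2.17, edgeR adjusted p = 0.026). The r was 0.0786 without reproductive replicate 1, 0.116 without control replicate 1 and 0.106 without vegetative replicate 1. Without the low-count filter, which let in many loci of low count, it was 0.0517. Of the 41 loci that rose after the single late shock, 31 also had a positive change in double-shock against vegetative-shock plants (75.6%). Their median log2 fold change there was 0.35, against 1.03 where they were called. Of the 71 that fell, 40 kept their sign (56.3%), with a median of -0.19 against -1.59. The first of each pair of medians is free of the selection that enlarges the second. Over both directions 71 of 112 kept their sign (63.4%), where simulations with no change gave 48.2% for 112 loci, with a maximum of 56.2%. That maximum, too, comes from loci drawn independently and may be too narrow a limit. No simulated value was made for the risers and fallers apart.

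Averaged over plants with and without the early shock, the late shock raised 41 loci and lowered 41, of which 49 changed at least 2-fold. LOC_Os01g64120 fell by 3.10 on the log2 scale (SE 0.16, edgeR adjusted p = 0.00031) and LOC_Os07g41060 had a log2 fold change of -4.26 (SE 0.59, edgeR adjusted p = 0.024). LOC_Os06g04920 rose by 5.27 on that scale, a fitted value that depends on the prior count since control had 4 reads (SE 0.49, edgeR adjusted p = 0.0060), and LOC_Os11g19240 (chromosome 11) by 2.26 (SE 0.31, edgeR adjusted p = 0.024). The count was 14 without reproductive replicate 2, 22 without reproductive replicate 1, 25 without double-shock replicate 1, 38 without control replicate 1 (12 of them rising), 43 without double-shock replicate 2 and 47 without vegetative replicate 1. DESeq2 called 321. With the term for multiply aligned reads LOC_Os11g19240 lost its call at a log2 fold change of 2.30 (SE 0.35), again with 3 residual degrees of freedom. LOC_Os07g41060 lost its call with robust quasi-likelihood, and both loci lost theirs without either reproductive or double-shock library or without vegetative replicate 1, while LOC_Os01g64120 kept its call in every alternative fit run.

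The interaction asks whether the shocks combined other than additively on the log2 scale. It was called for 18 loci, with 13 positive and 5 negative values, and 8 of the 18 lie on chromosome 2. At an unadjusted p below 0.05 there were 882 positive and 890 negative values. LOC_Os02g47470 stood at 56.1 ± 24.3 CPM in control, 5.82 ± 0.813 in vegetative-shock, 5.84 ± 0.144 in reproductive-shock and 23.8 ± 5.54 in double-shock plants (SD, n = 2; interaction 5.28, SE 0.45, edgeR adjusted p = 0.0066). LOC_Os02g52010 (chromosome 2) ran from 10.8 ± 0.931 CPM in control to 0.937 ± 0.0491, 0.501 ± 0.158 and 3.42 ± 2.08 CPM in the same order (interaction 6.26, SE 0.67, edgeR adjusted p = 0.027). LOC_Os02g45930 (chromosome 2) stood at 54.7 ± 4.28, 144.6 ± 23.6, 146.2 ± 12 and 43.3 ± 9.20 CPM (interaction -3.16, SE 0.26, edgeR adjusted p = 0.0066). LOC_Os09g37330 stood at 10.98 ± 5.29, 22.6 ± 0.0669, 19.96 ± 2.88 and 4.41 ± 0.390 CPM (interaction -3.21, SE 0.42, edgeR adjusted p = 0.042). In 13 of the 18 loci both single-shock groups lay below control and in 5 both lay above it, and in 14 the double-shock group lay nearer to control than either single-shock group. The median absolute log2 distance from control was 1.34 in vegetative-shock, 1.25 in reproductive-shock and 0.70 in double-shock plants. In simulated libraries with no change, a mean of 17.1 of the top 18 interaction loci likewise had both single-shock groups on the opposite side, and a mean of 14 had the double-shock group nearest to control. These tallies are what selection on the interaction gives. The simulated median distances averaged 1.07, 1.06 and 0.422, with maxima of 1.33, 2.06 and 0.98, so the vegetative distance lay just above its maximum and the others within their ranges. No locus was called without either reproductive library, and there were 4 calls without vegetative replicate 1, 7 without vegetative replicate 2, 5 without control replicate 2, 6 without double-shock replicate 1, 39 without double-shock replicate 2 and 55, of which 46 were positive, without control replicate 1. DESeq2 called 175, of which 98 were positive, and with a term for the share of multiply aligned reads there were 28 calls. LOC_Os02g52010 also lost its call without control replicate 2 or either vegetative library, and LOC_Os09g37330 without any 1 vegetative or double-shock library. In a 2-group fit of control and double-shock against single-shock libraries both lost their calls, as did LOC_Os02g47470.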

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

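The test of multiply aligned reads on the 18 calls, the test of placement by chance and the test of clustering along chromosome 2 were chosen only after the results were seen.

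The response to the late shock differed between plants without and with an earlier shock, by the interaction term, in 18 loci, with log2 values of 6.26 for LOC_Os02g52010, 5.28 for LOC_Os02g47470, -3.21 for LOC_Os09g37330 and -3.16 for LOC_Os02g45930. The tables argue against the share of multiply aligned reads as the cause, since 15 of the 18 loci stayed called with a term for it, among 28 calls. Simulations with no change gave at most 6 interaction calls, but chance cannot be excluded by 2-group fits, which leave the late-shock effect in the residual: the real split gave 2 calls, and 3 of the 35 splits gave as many, the others being the late-shock split, a structure of the samples, with 35, and one with the 3 libraries of many multiply aligned reads on 1 side, with 4. That both single-shock groups lay opposite to the interaction in all 18 loci is what selection of the calls would give, with a mean of 17.1 of 18 in simulations with no change. An effect of 1 deviating library cannot be told apart, since all 18 loci kept at least 50% of their interaction without any 1 library but a mean of 17.9 of 18 did so with no change simulated, and a biological interaction of the shocks stays open, as untested.

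Of the 18 interaction loci 8 lie on chromosome 2, where 2.15 would be expected from its share of tested loci. Chance placement was disfavoured narrowly by a one-sided exact hypergeometric test (p = 0.00059, and p = 0.043 after Benjamini-Hochberg adjustment over 72 tests of 12 chromosomes in 6 contrasts). With a term for the share of multiply aligned reads, 9 of 28 interaction calls lay on chromosome 2, against 8 of 18 without it. That argues against this share as the only cause. The list of 28 was not tested for enrichment, so a part played by the share stays open. A chromosome segment that differs between plants stays open, since 7 of the 8 loci lay within 514 of the 2180 tested loci (permutation p = 0.022 over all window sizes). All 8 spanned 1728, near the random median of 1751 (permutation p = 0.47). Uncalled loci in the window of 514 showed no excess, with an unadjusted p below 0.05 in 8.68% of cases against 10.4% elsewhere on the chromosome. A biological response stays open too, as untested, with LOC_Os02g45930 opposite in sign to the other 6 loci of the window.

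The HTSeq summary lines, which are outside the counted loci and served only to define the term for multiply aligned reads, held a share of multiply aligned reads of up to 13.81%, in reproductive replicate 2, against 13.52% and 9.601% in the control libraries.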

How the results depend on the processing

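The term for multiply aligned reads, the 2-group fits of 4 against 4 libraries, the use of a different control library for each comparison and the simulated checks of the filter and test were chosen after seeing the data. Counts of calls are given in the order of the reproductive, double-shock and vegetative groups against control, double-shock against reproductive, double-shock against vegetative, interaction, average reproductive shock and average vegetative shock. They were 112, 30, 6, 0, 13, 18, 82 and 0. With RLE factors or the filter of 1 CPM in 2 libraries, every count stayed within 1.5 times. Without a low-count filter they were 1291, 1119, 499, 501, 706, 646, 1224 and 301, with shared calls of 596 (reproductive and double), 362 (reproductive and vegetative) and 304 (double and vegetative) and correlations of 0.0517 (late shock) and -0.026 (early shock). In that fit the prior degrees of freedom were infinite instead of 4.77, and 1261 of the 1291 calls were among the loci of the filtered fit. For reproductive against control, the only contrast simulated here, 5 simulations with no change gave a mean of 62.2 false calls instead of 1.6. With the likelihood ratio test the counts were 603, 360, 175, 95, 164, 249, 519 and 18, with shared calls of 219, 136 and 84. Its mean number of false calls in those simulations of reproductive against control was 16.2. With DESeq2 they were 434, 232, 128, 72, 113, 175, 321 and 22, with shared calls of 149, 98 and 65, and its adjusted p was left undefined for up to 10969 loci. Robust quasi-likelihood moved the vegetative count to 14, double-shock against reproductive to 2, the interaction to 53 and the overlap of reproductive and vegetative calls to 13. Fits on the compared groups alone gave 175, 1 and 0 for reproductive against control, vegetative against control and double-shock against vegetative, and 1 shared call in each overlap with the vegetative group. A log2 fold change of at least 1 left 49 for the average reproductive shock. Deviations of same-numbered libraries from their group means correlated at -0.153 to 0.254 over the 6 pairs of groups, so the numbers were not taken as pairing libraries. The replicate block ended the calls of LOC_Os06g04920 and LOC_Os09g37330 in double-shock against vegetative, at log2 fold changes of 4.75 and -2.36, and of LOC_Os09g37330 in the interaction, at -3.25. It moved double-shock against control to 54, vegetative against control to 11 and the shared calls to 42, 11 and 6, and left the other counts within 1.5 times. The term for multiply aligned reads gave 6 for double-shock against vegetative and 28 for the interaction, and 2-group fits of 4 against 4 libraries gave 35 for the average reproductive shock and 2 for the interaction. With a different control library for each comparison, the 2 assignments shared 4 and 7 calls (reproductive and double), 2 and 4 (reproductive and vegetative) and 2 and 0 (double and vegetative). Leaving out 1 library gave ranges of 1 to 143, 4 to 49, 0 to 52, 0 to 17, 0 to 28, 0 to 55 and 14 to 89 for the first 7 counts. The average vegetative shock had 0 calls in each of those fits. The shared calls then ranged over 1 to 42, 0 to 45 and 0 to 18, and the correlations over 0.0786 to 0.236 and -0.192 to -0.082. Of 391 alternative fits of the 23 named results, none reversed, 276 stayed called and 115 did not, 86 of these when a library was left out. The 38 gene lists, with their alternatives, were not run, since no identifier has a gene name. Apart from the no-filter and likelihood ratio fits, the cause was not tested. With 2 libraries per group, a 2-fold change was recovered in 42% of simulated loci for reproductive against control, so smaller changes were mostly not detectable at this depth and replication.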

Other observations

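LOC_Os10g42770 and LOC_Os10g42780, neighbours among the tested loci of chromosome 10, were both among the calls for the reproductive shock, in the same direction. LOC_Os10g42770 stood at 0.406 CPM in control, 4.35 in vegetative-shock, 10.1 in reproductive-shock and 4.81 in double-shock plants, and LOC_Os10g42780 at 13.8, 91.8, 132.1 and 144.1 CPM in that order. The hypothesis that neighbouring loci change together was not borne out over the list of 112 calls, which held 2 adjacent pairs where random draws gave a mean of 0.67 (permutation p = 0.15). For the 82 calls of the average reproductive effect there were also 2 pairs, with a random mean of 0.37 (permutation p = 0.054).

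For the average effect of the reproductive shock, splits of the 8 libraries into 4 and 4 were compared in 2-group fits. The real split gave 35 calls and the highest of the other splits 4, so that 1 of the 35 splits, the real one, reached as many. That is the smallest share that 35 splits can give, and the test was also run for the vegetative shock and the interaction. Chance is therefore disfavoured but not excluded, even if the 8 libraries are independent. The labels do not say that they are. The 3 splits that keep both libraries of each group together, with 35, 2 and 0 calls, are too few for a share under 0.05. For the average effect of the vegetative shock the real split gave 0 calls. Any split reaches 0, as 35 of 35 did, so the splits decide nothing there. The highest other split had 35 calls and was that of the reproductive shock.

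By thresholds chosen after seeing the data, some loci stood at 5 CPM or more in 1 library and at least 8-fold above each of the others. There were 5 in double-shock replicate 1, 4 in control replicate 2, 1 in reproductive replicate 1 and 0 in each of the other 5 libraries.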
